A study of Homo sapiens with 3 samples.

How the data were processed

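The series holds 3 sequencing libraries of total RNA from Ishikawa human endometrial adenocarcinoma cells, made with the Lexogen QuantSeq kit, per the labels' protocols. QuantSeq primes cDNA at the poly(A) tail and yields about 1 fragment per transcript near its 3' end, so counts are not divided by transcript length, and transcripts without a poly(A) tail are captured only in part. Per the labels, DEHP was given at 10 µM for 8 h, and KRG, where used, at 500 µg/mL starting 1 h earlier. The deposited values are raw read counts per gene symbol, whole numbers in 1 table per library with no normalization by the authors that the tables show. The submitters' processing notes name Bowtie2, edgeR and the hg19 genome build, with no role or version. The aligner settings, the counting program, the annotation, the strand setting and any filter are not given in the sources used here.

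Each library was placed in its group by its sample label. The column heading inside each of the 2 treated tables names the other treatment, and the values were not used to decide between heading and label. Each table has 25737 rows with 24462 distinct symbols. Rows of the 286 symbols that stand on more than 1 row were summed; all such rows together held 1.24% of the counts. Every row names a gene. Counts total 13409653 in Control, 13424747 in the library labelled DEHP and 14408973 in the library labelled DEHP+KRG. The 10 most abundant genes took 4.67%, 4.86% and 4.76% of them, and ribosomal protein genes 13.0%, 12.2% and 12.5%. At these depths 3 reads, the most that a count of 0 allows, equal 0.224, 0.224 and 0.207 CPM. Trimmed-mean-of-M-values (TMM) factors from edgeR 4.0.16 were 0.999, 0.997 and 1.00. Under this scaling the median ratio of measured genes was 1.00, 1.00 and 0.997 in the 3 comparisons.

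With 1 library per group there are no residual degrees of freedom, so no model test was run and edgeR served for the factors alone. A gene was counted as higher or lower when it had at least 30 reads in the higher library, a ratio of TMM-scaled CPM of at least 2, and a 95% counting interval of the ratio that excluded 1. The interval is the exact Clopper-Pearson interval of the share of the pooled reads that came from the first library, rescaled by effective library sizes. This rule, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The numbers expected with no difference came from 100 simulated sets, drawn with counting noise alone and, as an addition made after seeing the data, with independent variation of each library whose size was set by the scatter between the 3 libraries. That scatter contains any true differences. It is the typical scatter in each range of counts, so genes that vary more than is typical are not represented. It was measured at mean counts of 30 or more, where it grew as counts fell. Genes with lower means were given the value of the range from 30 to 100 reads, which may be too small for them. Whether the second simulation has more or less variation than replicate libraries would is unknown. For genes standing apart, a library had to pass the rule against both others in the same direction.

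Genes named are the 12 higher and 12 lower in each comparison whose interval limit nearest to 1 lies furthest from 1, passing over unnamed loci. Added to these are up to 4 members of each list discussed with the largest such limit, and 12 genes named whatever their values (PTGS2, IL6, CXCL8, IL1B, TNF, CCL2, NFKBIA, RELA, ESR1, PGR, CYP1A1 and HMOX1). Some genes that this rule selects are not reported here. Among the 61 ranked genes 56 were found by symbol in GENCODE 29, and 20 of those have exons that overlap another gene on either strand. Their reads cannot be told apart without the strand setting, nor with it where the overlap is on the same strand. Genes whose counts matched those of another gene within 10 table rows to within 5% in all libraries were treated as sharing reads; there were 337. No coordinates are given, because the reference at hand is GRCh38 and the tables were made on hg19.

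The 36 gene lists cover inflammatory, hormone, xenobiotic, stress, metabolic, cell cycle and housekeeping genes and markers of other cell types. For members with at least 30 reads over the 3 libraries the median log2 ratio was taken, after adding 0.5 to each count, and ranked among 10000 random lists of the same size drawn within 20 bins of mean expression. Lists with under 5 measured members, of which the fixed lists had 4, are given as counts. Lists of liver genes were added after the ALB counts had been seen. GC content of the last 500 nt and transcript length came from GENCODE 29 transcripts for 97.5% of measured genes. Log2 ratios correlated with that GC content across genes at Spearman -0.11, -0.19 and -0.07 in the 3 comparisons, and with transcript length at 0.019, 0.012 and -0.007.

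Alternatives were total-count, DESeq2 1.42.0 and upper-quartile scaling, minimum counts of 10, 100 and none, ratios of 1.5 and 3, a 99.9% interval, libraries thinned to 1 depth, and reads of a shared library split between comparisons. Lists were repeated with the other scalings, a summed count of 100, and the mean. After seeing the data, 4 were added: the highest row per symbol, leaving out genes that share reads, the simulation with library variation, and a correction for 3' GC content and length. Alternatives planned for normalized values were not run, since the tables hold counts.

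The counting rule was tested on simulated libraries with 200 changed genes, 50 for each fold. For DEHP against Control, over 12702 genes, it recovered 0% of genes changed 1.5-fold, 48% at 2-fold, 98% at 3-fold and 96% at 4-fold, and counted 13 unchanged genes. A true 2-fold change lies on the threshold itself. The 13 unchanged genes are near the 13.3 that counting noise alone gave, against 86.0 with independent variation of each library. They are therefore not a rate of false calls for real libraries. For DEHP+KRG against Control it recovered 50% at 2-fold and 98% at 3-fold over 12766 genes, with 10 unchanged genes, and for DEHP+KRG against DEHP 50% and 98% over 12741, with 12. A simulated list of 30 genes shifted by 0.20 on the log2 scale lay at the 100th percentile of its random lists. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.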

Results

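Polyadenylated RNA from Ishikawa cells, an established human endometrial adenocarcinoma line, was measured by 3' end sequencing in 3 libraries, 1 for each condition. The conditions were cells labelled Control, without DEHP or KRG, cells given 10 µM DEHP for 8 h, and cells given 500 µg/mL KRG for 1 h before the same dose of DEHP. The Control label names no vehicle, so whether these cells received one is not known here. DEHP is di-(2-ethylhexyl) phthalate, a plasticizer used in polyvinyl chloride, and KRG is Korean Red Ginseng extract. The study was set up around inflammatory gene expression under DEHP and its course under KRG. The libraries held 13409653 reads in Control, 13424747 in the library labelled DEHP and 14408973 in the library labelled DEHP+KRG, over 17730, 17822 and 17652 gene symbols with at least 1 read. Across gene symbols, which are not independent replicates, the Spearman correlation was 0.981 for each pair of libraries.

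In both treated tables the column heading named the other treatment, so that the table recorded for the DEHP sample was headed as the combination and the reverse. Groups follow the sample labels throughout, and each treated library is therefore called the library labelled DEHP or the library labelled DEHP+KRG. If the headings rather than the labels were right, the comparisons with Control would change places and every direction between the treated libraries would turn round. What the treated libraries share against Control does not depend on this. With 1 library per condition no difference below has a replicate check, no p-value is given, and folds carry 95% counting intervals. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Among genes with a mean of 1000 or more reads, log2 ratios of DEHP against Control had a robust SD of 0.131. Counting alone would give 0.047 there. Intervals that exclude 1 are therefore frequent among abundant genes, whatever list they stand on.

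The first comparison, of the library labelled DEHP with Control, addressed what the phthalate did to the transcriptome. Heme oxygenase 1 (HMOX1), the enzyme that degrades heme and a target of the antioxidant factor NRF2, was 4.17-fold higher in the library labelled DEHP (interval 3.09 to 5.72; 225 against 54 reads). The albumin gene ALB was 16.2-fold higher (8.83 to 33.0), from 11 reads in Control to 178. KRT17, a keratin of stressed epithelia, was 2.98-fold higher (2.12 to 4.26), and RSPO1, a secreted amplifier of Wnt signalling, was 2.42-fold higher (2.03 to 2.91). The interferon-inducible GTPase gene GBP1 was 2.79-fold higher (1.99 to 3.97). Lower in the library labelled DEHP were RNU4ATAC, the U4atac RNA of the minor spliceosome, by 2.96-fold (2.75 to 3.19), the interferon-induced exonuclease gene ISG20 by 5.50-fold (2.27 to 16.0) and the membrane mucin gene MUC4 by 3.41-fold (2.09 to 5.76). Small nuclear RNAs such as RNU4ATAC lack a poly(A) tail and are captured only in part here. Its reads may therefore differ between libraries through capture and not through its amount.

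The other leading genes higher in the library labelled DEHP were the muscle actin gene ACTA1 at 3.54-fold (1.96 to 6.75), the immediate-early nuclear receptor gene NR4A1 at 3.32-fold (1.96 to 5.87), DAPP1 at 3.10-fold, the guanine deaminase gene GDA at 3.06-fold, BLZF1 at 3.0-fold, CALCOCO1 at 2.80-fold and HYPK at 2.06-fold. The other leading genes lower in that library were ABHD16B by 4.18-fold, NIPSNAP3B by 4.0-fold, the glutamate receptor gene GRIA4 by 3.91-fold, SCUBE3 by 3.63-fold, the betaine transporter gene SLC6A12 by 3.50-fold, the Wnt ligand gene WNT11 by 3.20-fold and the fatty acid hydroxylase gene FA2H by 3.0-fold. The growth factor receptor gene FGFR3 was lower by 2.19-fold (1.73 to 2.79) and the butyrophilin gene BTN3A1 by 2.36-fold (1.70 to 3.31). In the annotation HYPK overlaps exons of SERF2 on the same strand, where a strand setting would not separate the reads. HYPK, NR4A1, ABHD16B, SLC6A12 and WNT11 overlap genes on the opposite strand, and reads there cannot be assigned to 1 gene without the strand setting. In total 63 genes were higher and 73 lower by at least 2-fold, among 12763 genes with at least 30 reads in either library. Their median count in the higher library was 46.5 reads. Simulated unchanged libraries with counting noise alone gave 13.3 such genes on average, and simulated libraries that also varied independently of each other gave 86.0, with a range of 51 to 107.

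Of 25 measured genes of the NRF2 antioxidant list 20 were above Control in the library labelled DEHP, 16 had intervals wholly above 1 and 4 wholly below (among them ABCC1 and AKR1C2 at 0.792-fold and 0.772-fold), and 1, HMOX1, passed 2-fold. GCLM, a subunit of the enzyme that limits glutathione synthesis, was at 1.6-fold (1.5 to 1.7), the sulfiredoxin gene SRXN1 at 1.53-fold (1.45 to 1.61), the thioredoxin reductase gene TXNRD1 at 1.53-fold (1.45 to 1.61) and the cystine transporter gene SLC7A11 at 1.41-fold (1.34 to 1.48). The median ratio of the list was 1.11, above all 10000 random lists of like size and expression, a rank that describes these libraries and tests no treatment. The aryl hydrocarbon receptor (AhR) list had 9 of 10 measured members above Control and none past 2-fold, with a median ratio of 1.30 that also lay above all 10000 random lists. Its members include the xenobiotic-metabolising genes CYP1B1 at 1.5-fold (1.46 to 1.54) and CYP1A1 at 1.35-fold (1.17 to 1.55), and the receptor's repressor AHRR at 1.66-fold (1.18 to 2.36). In the same library liver genes other than ALB with under 60 reads, from a list added after ALB was seen, had 101 reads in total, against 20 in Control and 24 in the library labelled DEHP+KRG, and RNA from other cells was not tested as a source of the list shifts.

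Immediate-early genes, which growth factors and stress switch on within minutes, had a median ratio of 1.23, above all 10000 random lists. Of 30 measured members 12 had intervals above 1 and 4 below, and 1, NR4A1, passed 2-fold on at least 30 reads. JUN stood at 1.89-fold (1.64 to 2.17), CTGF at 1.81-fold (1.66 to 1.97), EGR1 at 1.65-fold (1.39 to 1.97) and CYR61 at 1.64-fold (1.6 to 1.7). The epithelial-mesenchymal list, which shares CTGF and CYR61 with it and includes the smooth-muscle actin-binding gene TAGLN at 1.57-fold (1.49 to 1.65), had a median ratio of 1.16, above all 10000 random lists. Heat shock genes had 19 of 21 measured members above Control and a median ratio of 1.09, with 19 of 10000 random lists as high. Among them the chaperone genes HSPA8 and HSPA1B stood at 1.25-fold (1.22 to 1.28) and 1.29-fold (1.17 to 1.41). The integrated stress and unfolded protein response list had a median ratio of 1.07, with 10 random lists as high, and included ATF3 at 1.51-fold (1.21 to 1.88). The JAK-STAT feedback list stood at 1.14, with 5 random lists as high, and hypoxia and glycolysis genes at 1.07, with 93 as high. Ribosomal protein genes had a median ratio of 0.968, with 180 random lists as low, and of 50 members 29 had intervals below 1 and 10 above; the list lay inside after the correction for 3' GC content and length. In all 11 of 32 lists lay outside the middle 95% of their random lists. By chance 1.6 would be so if the genes of a list varied independently of each other, as in the random lists. Members that vary together would raise that number, and 50 genes stand on more than 1 list.

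**Figure D1:**
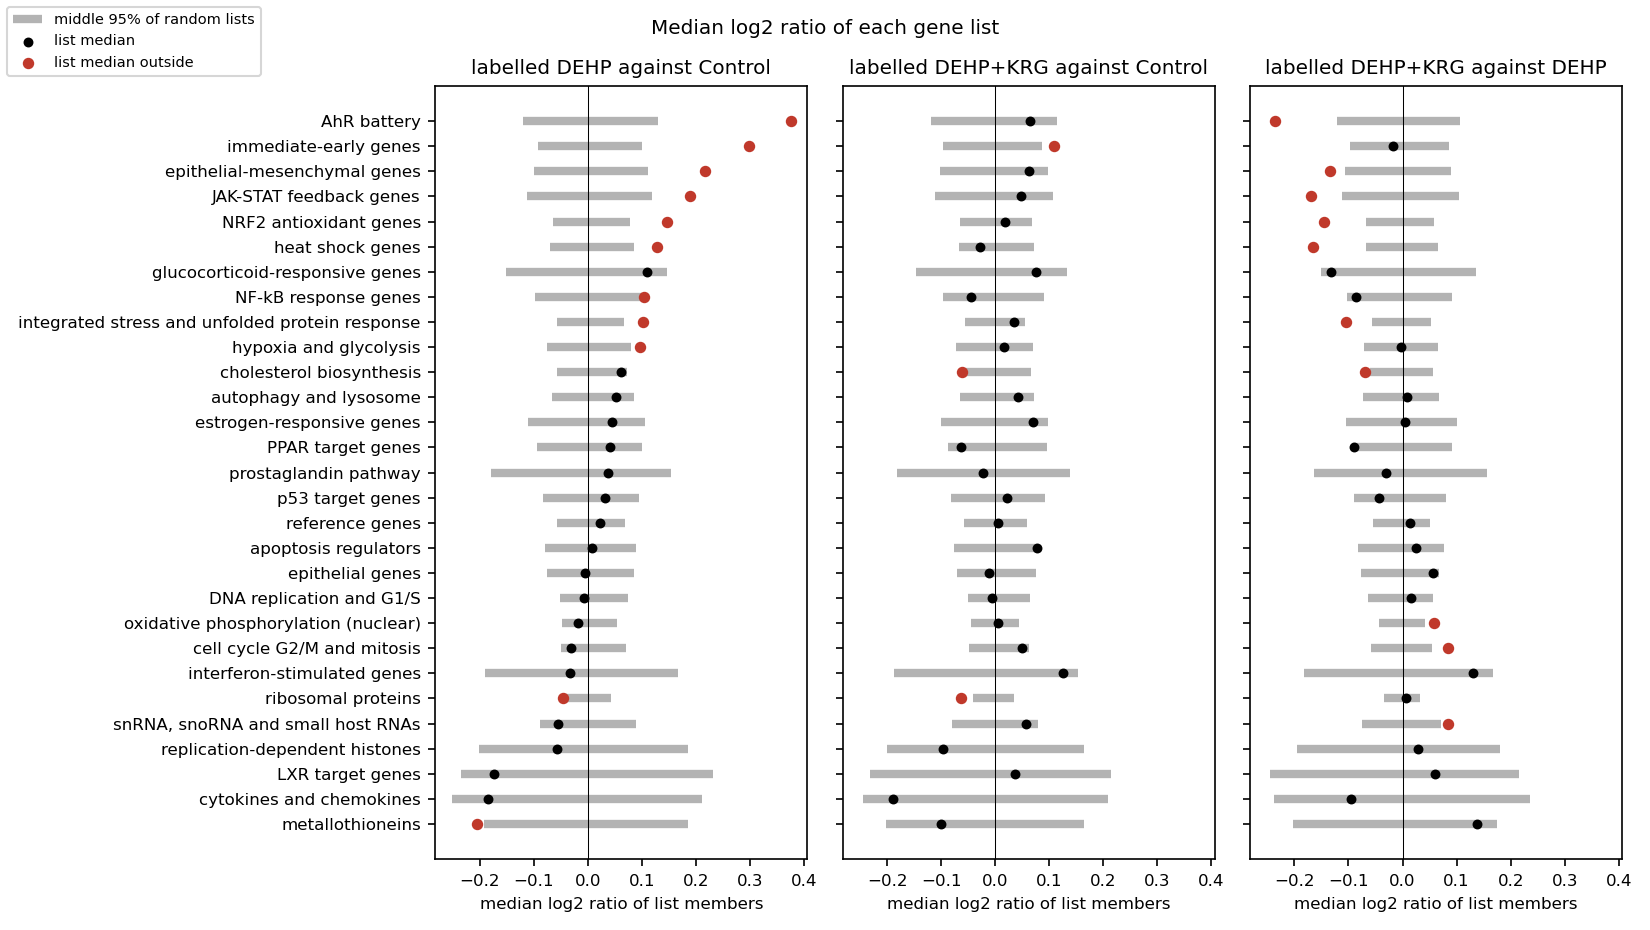
Median log2 ratio of the members of each gene list (x axis) in the 3 comparisons between libraries, with the middle 95% of random lists of like size and expression as grey bars. Red points lie outside the bars: for DEHP against Control the AhR list lies furthest to the right, with a median ratio of 1.30, and for DEHP+KRG against DEHP it lies furthest to the left, with 0.849.

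Of the inflammatory genes, the subject of the study, several were at or near the floor of these libraries, and no member of the cytokine, prostaglandin and NF-kB lists differed by 2-fold on at least 30 reads in the library labelled DEHP. CCL2 had no read in any library, which allows up to 0.224 CPM (counts scaled to a common library size) in Control. IL6 had 1 read in Control and 0 in the library labelled DEHP, CXCL8 and IL1B had 0 and 1, and TNF had 4 and 0, so differences in these cytokine genes were not detectable at this depth. PTGS2, which encodes the inducible cyclooxygenase, was at 0.889-fold (0.625 to 1.26), and the NF-kB subunit gene RELA was at 1.08-fold (0.990 to 1.17). NFKBIA, the gene of an NF-kB inhibitor that NF-kB itself induces, was at 0.892-fold (0.822 to 0.968). Of 12 measured cytokine and chemokine genes 2 had intervals above 1 and 3 below, among them LIF at 1.57-fold (1.13 to 2.19), TGFB2 at 1.34-fold (1.09 to 1.65), IL15 at 0.589-fold (0.362 to 0.942) and TGFB3 at 0.569-fold (0.360 to 0.888). Their median ratio of 0.880 lay inside the middle 95% of random lists. The prostaglandin pathway list likewise lay inside, at 1.03. The NF-kB response list had a median ratio of 1.08, with 217 random lists as high; 7 of 29 members had intervals above 1, among them the inhibitor gene NFKBIB at 1.35-fold (1.18 to 1.55), and 3 below. It came to lie inside when members with under 100 reads were left out, and also when 3' GC content and transcript length were taken into account. The estrogen receptor gene ESR1 was at 0.840-fold (0.695 to 1.01), and the progesterone receptor gene PGR was 2.14-fold higher (1.10 to 4.38) on 30 against 14 reads.

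**Figure D2:**
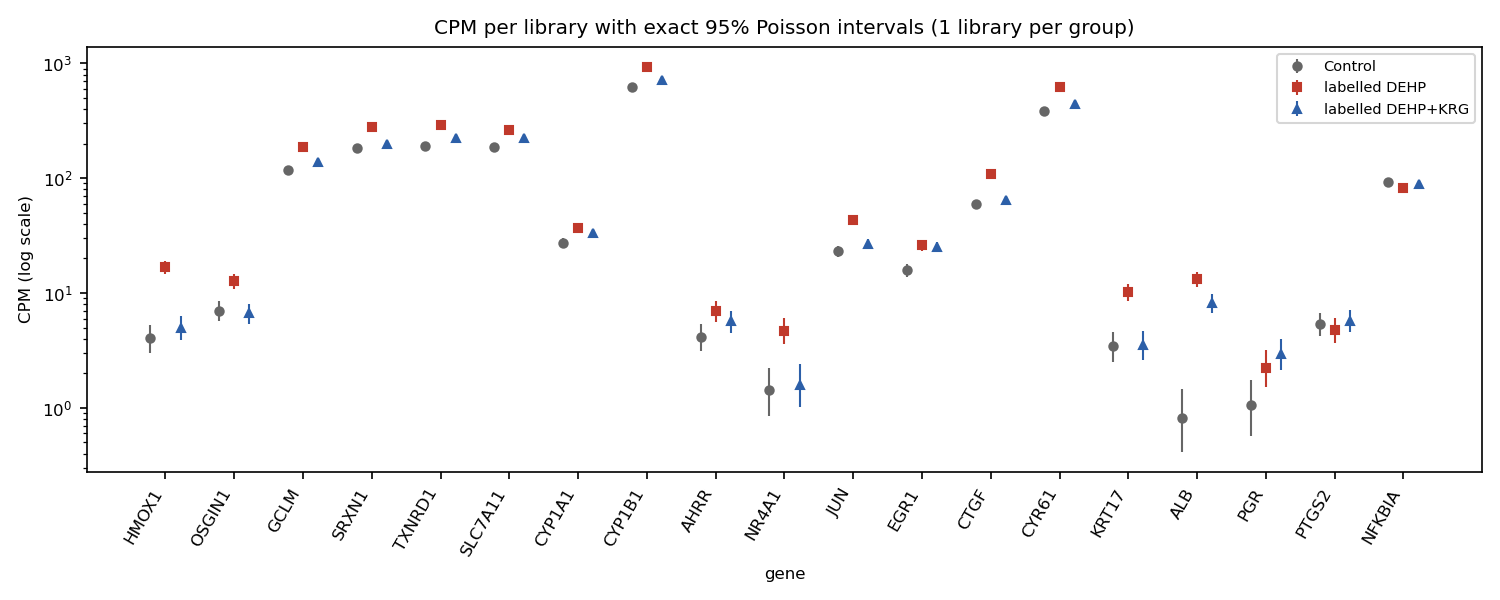
CPM of selected genes (log axis) in the 3 libraries, 1 symbol per library, with exact 95% Poisson intervals for counting error. HMOX1, KRT17 and NR4A1 are highest in the library labelled DEHP, at 4.17, 2.98 and 3.32 times Control, while PTGS2 has overlapping intervals in all 3 libraries.

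The second comparison set the library labelled DEHP+KRG against Control, for what remained of the DEHP difference with KRG present; without a KRG-only library it cannot separate the agents. ALB was again higher, by 9.93-fold (5.35 to 20.4; 118 against 11 reads), and PGR was 2.84-fold higher (1.53 to 5.63; 43 against 14 reads). The lysophospholipid acyltransferase gene LPCAT4 was 2.25-fold higher (1.69 to 3.03), and the mitochondrial fatty acid oxidation gene ACADL 2.12-fold (1.55 to 2.93). The small noncoding RNAs SNAR-C5 and SNAR-E were lower by 2.33-fold (2.07 to 2.63) and 2.08-fold (1.83 to 2.38). They are named by rank, and of the 28 SNAR symbols with reads 23 did not pass the rule in any comparison. SNAR-C1 and SNAR-C2 carried the same counts in every library, 292 in Control and 119 here, so reads shared between near-identical copies cannot be assigned. HMOX1 stood at 1.23-fold (0.856 to 1.79), KRT17 at 1.03-fold (0.676 to 1.56) and NR4A1 at 1.12-fold (0.584 to 2.18) of Control.

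Among the other leading genes higher than Control, AFF2 was at 11.4-fold (3.62 to 57.9) on 37 against 3 reads and the cancer-testis antigen gene MAGEA8 at 5.93-fold (2.29 to 19.5) on 32 against 5. KHDC1 and the phosphatidylinositol kinase gene PIP5K1B were both 3.70-fold higher, PHYHIPL 3.62-fold, ZNF462 3.47-fold, the embigin gene EMB 3.39-fold, and TRIM52 and CNKSR3 2.31-fold. Lower were RASL10B by 4.10-fold, the potassium channel gene KCNJ4 by 3.60-fold, SP140L by 3.24-fold, MORN1 by 3.10-fold, ZNF57 by 3.01-fold, RDM1 by 2.72-fold, the steroid dehydrogenase family gene HSD17B8 by 2.61-fold and the tetraspanin gene TSPAN10 by 2.58-fold. Exons of KHDC1 overlap another gene on the same strand, and those of KHDC1, ACADL, PIP5K1B, PHYHIPL, ZNF462, TRIM52, KCNJ4, ZNF57 and TSPAN10 overlap genes on the opposite strand. In total 50 genes were higher and 70 lower among 12831. Simulated libraries gave 13.1 with counting noise alone and 87.1 with independent variation, with a range of 67 to 122 that takes in the observed 120.

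In this comparison 3 of 32 lists lay outside the middle 95% of random lists, and 5 did so once 3' GC content and length were taken into account. Ribosomal protein genes had a median ratio of 0.957, with 6 of 10000 random lists as low, and 32 of 50 members had intervals below 1 and 10 above; RPS3 stood at 0.769-fold (0.758 to 0.780) and RPL32 at 0.821-fold (0.811 to 0.831), while RPS27A stood at 1.08-fold (1.07 to 1.09). Cholesterol biosynthesis genes had a median ratio of 0.958, with 146 random lists as low, and included the desaturase gene FADS1 at 0.844-fold (0.794 to 0.898). Immediate-early genes had a median ratio of 1.08, with 77 random lists as high, EGR1 being at 1.61-fold (1.36 to 1.92); the mean of the list lay inside. The NRF2, AhR and heat shock lists had median ratios of 1.01, 1.05 and 0.981, all inside. Of measured NRF2 members 8 had intervals above 1 and 4 below, and of AhR members 3 above and 1 below. Some members named for the library labelled DEHP thus remained above Control. CYP1B1 stood at 714 CPM (700 to 728) against 618 (605 to 632), and GCLM at 139 (133 to 146) against 119 (113 to 125). Cytokine and chemokine genes stood at 0.877, prostaglandin genes at 0.984 and NF-kB response genes at 0.969, all inside, and PTGS2 was at 1.07-fold (0.769 to 1.48).

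**Figure D3:**
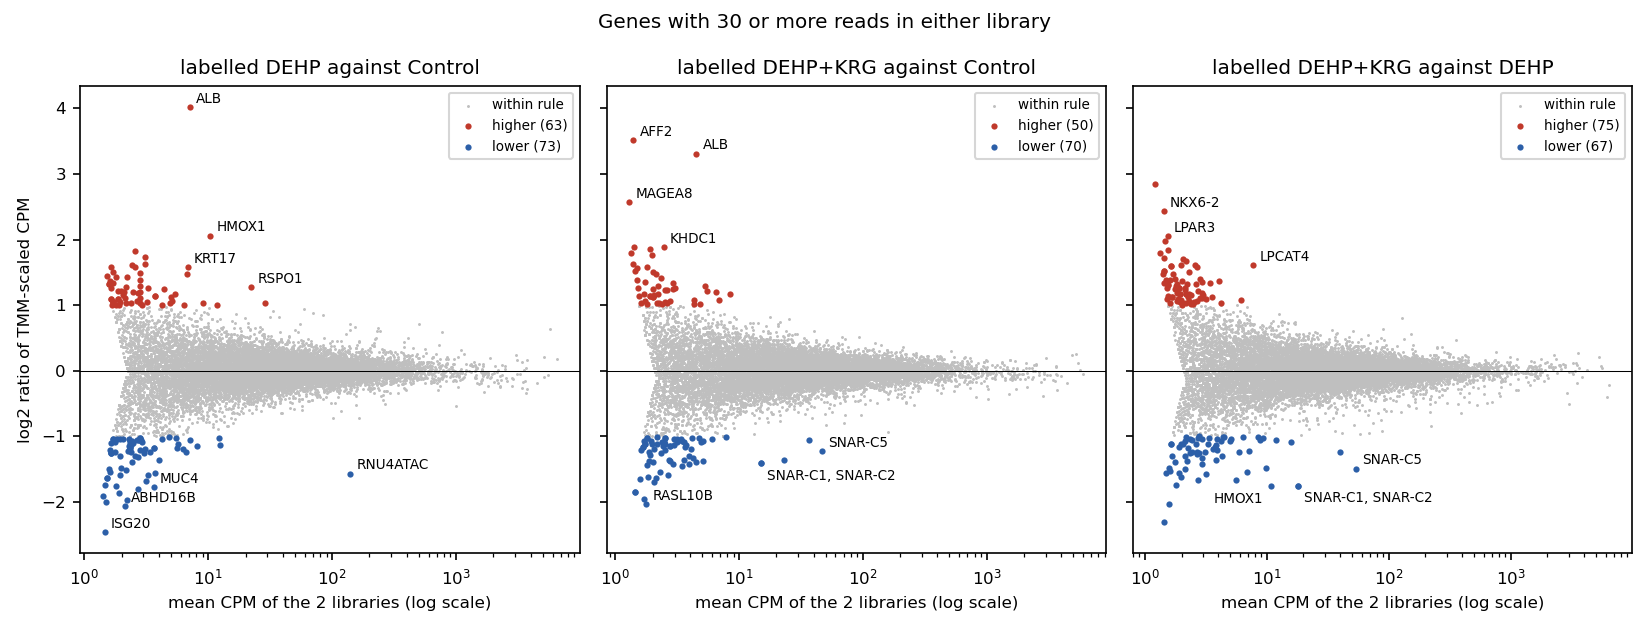
Log2 ratio of scaled CPM (y axis) against mean CPM (log x axis) for genes with 30 or more reads in either library, 1 panel per comparison. Coloured points are the genes at least 2-fold higher (63, 50 and 75) or lower (73, 70 and 67), and most of them lie at low CPM.

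The third comparison set the library labelled DEHP+KRG against the library labelled DEHP, for what KRG changed under DEHP; its signs are the ones that turn if the labels are exchanged. HMOX1 was 3.38-fold lower in the library labelled DEHP+KRG (2.58 to 4.47; 72 against 225 reads). Lower too were DUSP8, a phosphatase gene that acts on stress kinases, by 3.16-fold (2.18 to 4.67), NR4A1 by 2.96-fold (1.81 to 5.00), KRT17 by 2.90-fold (2.09 to 4.09) and the keratin gene KRT80 by 2.12-fold (1.73 to 2.60). SNAR-C1 and SNAR-C2, which carry the same counts, were lower by 3.37-fold (2.73 to 4.18), SNAR-C5 by 2.81-fold, SNAR-D by 2.80-fold and SNAR-E by 2.36-fold. Higher were LPCAT4 by 3.05-fold (2.22 to 4.26), AGR2, which encodes a secretory disulfide isomerase, by 2.53-fold (1.6 to 4.1), and the lysophosphatidic acid receptor gene LPAR3 by 4.16-fold (1.90 to 10.4).

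The other leading genes higher in the library labelled DEHP+KRG included the homeobox gene NKX6-2 at 5.40-fold on 35 against 6, NIPSNAP3B at 3.93-fold, the metalloproteinase gene MMP19 at 3.27-fold, TMEM86A at 3.17-fold, PHYHIPL at 3.06-fold, SOHLH2 at 3.05-fold and ZHX2 at 2.59-fold. SOHLH2 shares its exons with the readthrough gene CCDC169-SOHLH2, which stood at 2.98-fold. The other leading genes lower were the pseudogene EIF3IP1 by 4.94-fold, on 7 against 32 reads, and the calcium channel gene CACNA1D by 4.08-fold, on 9 against 34. Exons of NKX6-2, MMP19, TMEM86A, PHYHIPL, CACNA1D and NR4A1 overlap genes on the opposite strand. In total 75 genes were higher and 67 lower among 12828, against 12.9 in simulations with counting noise and 86.3 (57 to 111) with independent variation. At a minimum of 100 reads 18 genes were left, 2 higher and 16 lower.

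Several of the stress lists stood on the other side in this comparison. Immediate-early genes, at a median ratio of 0.989, and hypoxia and glycolysis genes, at 0.998, lay inside their random lists. Single immediate-early genes were not flat: of 30 measured members 6 had intervals above 1 and 8 below. NR4A1 and ATF3, the latter at 0.48-fold (0.378 to 0.606), passed 2-fold lower. JUN was at 0.609-fold (0.534 to 0.694) and CTGF at 0.597-fold (0.549 to 0.649), while EGR1 stayed at 0.976-fold (0.841 to 1.13). NRF2 genes had a median ratio of 0.904, below all 10000 random lists, with 17 of 25 members below 1 beyond their intervals and 2 above, among them the drug efflux gene ABCC1 at 1.49-fold (1.31 to 1.69); GCLM was at 0.741-fold (0.698 to 0.786), SRXN1 at 0.722-fold (0.687 to 0.758) and OSGIN1 at 0.520-fold (0.40 to 0.67). Heat shock genes had a median ratio of 0.892, also below all 10000, with HSPA8 at 0.815-fold (0.797 to 0.833). All 10 measured AhR genes were below 1, with a median ratio of 0.849 and 6 random lists as low; CYP1B1 was at 0.769-fold (0.749 to 0.790) and CYP1A1 at 0.905-fold (0.796 to 1.03). The integrated stress list stood at 0.931, with 2 random lists as low, JAK-STAT feedback genes at 0.889, with 24, and epithelial-mesenchymal genes at 0.911, with 86. The first 2 of these lay inside when the mean was used. Cholesterol biosynthesis genes stood at 0.953, with 123 random lists as low. Mitotic genes stood at 1.06, with 11 random lists as high, and nuclear genes of oxidative phosphorylation at 1.04, with 24. All comparisons with the library labelled DEHP share its reads, so any chance deviation of that library appears in both with opposite sign.

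PTGS2 was at 1.20-fold (0.856 to 1.69) and NFKBIA at 1.09-fold (1.00 to 1.18) in the library labelled DEHP+KRG relative to DEHP. Cytokine and chemokine, prostaglandin and NF-kB response lists had median ratios of 0.936, 0.980 and 0.941, and all 3 lay inside the middle 95% of random lists.

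Of the 136 genes that differed between the library labelled DEHP and Control, 32 differed by the same rule in the opposite direction between DEHP+KRG and DEHP. Of these 13 were higher in the library labelled DEHP, among them GBP1, ACTA1 and DUSP8, and 19 were lower, among them BTN3A1, FA2H and ABHD16B. Both comparisons use the same DEHP reads, and with these split between them, which also lowers the DEHP depth of each, the number was 16 (11 to 21 over 100 draws). The library labelled DEHP+KRG stood apart from both others in 30 genes, and Control in 27, so a library standing apart was about as frequent for each of the 3. Both treated libraries were higher than Control in 12 genes and lower in 15, 27 in all. Simulated unchanged libraries with independent variation, sharing 1 Control as here, gave 14.2 such genes (6 to 23), and independent lists with no shared Control would have 0.243 and 0.395 in common. Log2 ratios of the treated libraries to Control correlated across 12940 genes with r = 0.485 (Spearman 0.459) and a covariance of 0.0403. Simulated unchanged libraries sharing the same Control gave r = 0.507 (0.472 to 0.537) with counting noise and 0.503 (0.467 to 0.522) with independent variation. The observed r lay inside both ranges. Simulated covariances were 0.0144 and 0.0363 on average, and the highest was 0.0387. The observed covariance was higher while r was not, so it does not show a difference shared by the treated libraries. Part of it may come from the shared Control library.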

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

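The highest row per symbol, the removal of genes that share reads, the simulation with library variation, and the GC and length correction were chosen after the results were seen; the other alternatives were planned. Counts of genes past the rule followed the count minimum, the ratio and the interval, as their construction requires. For DEHP against Control, DEHP+KRG against Control and DEHP+KRG against DEHP in turn, they were 404, 384 and 403 at a minimum of 10 reads, 524, 503 and 511 with none, 18, 13 and 18 at 100, 578, 503 and 562 at a ratio of 1.5, 21, 19 and 23 at 3, and 65, 62 and 69 with the stricter interval. The other 18 recounts, with other scalings, thinning, the highest row per symbol or without shared reads, stayed within 1.5 times. The 32 genes that differed in the library labelled DEHP and back again became 5 at 100 reads, 180 at a ratio of 1.5 and 16 with the DEHP reads split. The split removes shared counting noise and also lowers the DEHP depth, and these were not separated. It leaves that library's own variation in both comparisons. The correlation of 0.485 became 0.261 with the Control reads split, which leaves that single library's own variation in both ratios; no simulated value stands beside it. After the GC and length correction 5 lists lay outside for DEHP+KRG against Control, in place of 3; the cause was not tested. The metallothionein list turned from a median log2 ratio of -0.20 to a mean of 0.0798 for DEHP against Control, since MT1E (3 to 23 reads) weighs on the mean. In 8 of the other recomputed values a list that had been outside its random lists came to lie inside, and in 111 it stayed outside. Some of the 111 come from other scalings, which shift a list and its random lists alike and so could not move it inside. All 505 recomputed log2 ratios of named genes stayed within their counting intervals. Depth limits the cytokine genes with 0 to 4 reads, whose differences were not detectable. No paired analysis was possible because each group has 1 library, and leaving out a library is impossible for the same reason.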

Other observations

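The tests of library size, of the single Control library, of exchanged labels and of counting noise were chosen after the values they use had been seen, as were the lists of liver genes, the simulation with library variation and the GC and length correction. Metallothionein genes, which bind zinc and copper and answer to metals, did not move together in the library labelled DEHP. MT1X was at 0.757-fold of Control (0.694 to 0.825) and MT2A at 0.903-fold (0.868 to 0.939), while MT1E was at 7.67-fold (2.32 to 39.9) on 23 against 3 reads. The median ratio of the list was 0.868, with 198 of 10000 random lists as low, though inside after the GC and length correction, and for DEHP+KRG against Control it was 0.932, inside the middle 95%. The list of small nuclear and nucleolar RNAs and their host genes, which also holds MALAT1, had a median ratio of 1.06 for DEHP+KRG against DEHP. There 108 random lists were as high, though the mean lay inside. Its leading members in that comparison were the host genes SNHG6, SNHG7, SNHG8 and ZFAS1, so the median may say little about the small RNAs themselves. The epithelial transcription factor gene ELF3 was lower in the library labelled DEHP than in Control by 1.65-fold (1.52 to 1.78), and the amino acid transporter gene SLC7A5 was higher by 1.42-fold (1.37 to 1.48). In the library labelled DEHP+KRG SLC7A5 was at 0.908-fold of Control (0.871 to 0.946).

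Lists of estrogen-responsive genes, PPAR targets, LXR targets, glucocorticoid-responsive genes, p53 targets, interferon-stimulated genes, DNA replication, epithelial genes, apoptosis regulators, autophagy and lysosome genes, histones and reference genes lay inside the middle 95% of random lists in all 3 comparisons without the GC and length correction. With it, 3 came to lie outside: PPAR targets for DEHP+KRG against DEHP, at a median log2 ratio of -0.10, and for DEHP+KRG against Control estrogen-responsive genes at 0.11 and autophagy and lysosome genes at 0.08. For DEHP against Control their median ratios were 1.03, 1.03, 0.887, 1.08, 1.02, 0.977, 0.995, 0.997, 1.01, 1.04, 0.961 and 1.02 in that order. Single reference genes were not flat. Of 27 members 6 had intervals above 1 and 6 below in this comparison, and 7 and 4 for DEHP+KRG against DEHP. ACTB was at 1.2-fold (1.17 to 1.23) and GAPDH at 1.12-fold (1.11 to 1.14) of Control in the library labelled DEHP. For DEHP+KRG against DEHP they were at 0.814-fold (0.796 to 0.832) and 0.788-fold (0.777 to 0.799). Targets of PPAR, nuclear receptors that phthalate metabolites are known to activate, had none of 22 measured members past 2-fold on at least 30 reads in any comparison; below that minimum, UCP3 was at 2.88-fold of Control (1.24 to 7.44) on 23 against 8 reads in the library labelled DEHP. Of the PXR and CAR target list 3 of 14 genes were measured, and 3 were above Control in the library labelled DEHP, with 1 interval above 1. The mitochondrial list could be matched for 3 of 34 genes, MTRNR2L1, MTRNR2L2 and MTRNR2L8, nuclear copies of a mitochondrial ribosomal RNA, at 1.21-fold, 1.13-fold and 1.19-fold in the library labelled DEHP. Markers of leukocytes summed to 8.36, 8.29 and 7.54 CPM in Control, DEHP and DEHP+KRG, those of endothelial cells to 6.65, 5.45 and 5.60, of erythroid cells to 1.4, 2.5 and 1.6, of stromal fibroblasts to 335, 328 and 348, and of endometrial epithelium to 1605, 1603 and 1653.

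ALB had 11 reads in Control, 178 in the library labelled DEHP and 118 in the library labelled DEHP+KRG, and RNA from liver cells is a candidate source. Against it for DEHP+KRG, the other 16 genes of a hepatocyte list changed by -0.194 ± 3.98 CPM while ALB gained 7.34 ± 1.55; in the library labelled DEHP they changed by 3.08 ± 4.17 while ALB gained 12.5 ± 2.01. In the library labelled DEHP it stays open: the 14 list members under 60 reads went from 20 to 101 reads, APOB from 4 to 27 and AFP from 2 to 12, against 24 in DEHP+KRG, and for the members under 60 reads of a second list chosen after that the summed ratio was 1.46 (1.08 to 1.99; 74 to 108 reads), which met the bounds set for both outcomes. The whole second list, most of whose 1420 Control reads come from a few genes that these cells express, stood at 0.893 (0.828 to 0.964). Scaling is argued against, since the lowest interval limit of the ALB ratio over 4 scalings was 5.34, but with 1 Control library a chance low ALB count there cannot be told apart from a difference shared by both treatments, and such a difference remains an untested hypothesis.

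The library labelled DEHP differed from Control in 32 genes for which DEHP+KRG stood at the side of Control. Under the labels this is the form a protective effect of KRG would take. The number was 16 (11 to 21) when the DEHP reads were split so that no read served both comparisons, at a lower depth in each. Independent variation of each library gave 13.8 such genes in simulation, and 23 at most, so the observed 32, with all reads, is higher. Some of the 32, such as DACT1 on 12, 34 and 14 reads, have means under 30. The scatter used in the simulation was not measured there, so the simulated number may be too low. The same count for Control was 27 and for DEHP+KRG 30. Under the labels a protective effect would raise neither. A DEHP difference that KRG left in place would raise the 27, however, and an effect of KRG itself the 30. These counts are therefore not a clean measure of library variation. They also hold linked symbols: SNAR-C1 and SNAR-C2 with the same counts in the 30, and MMP19 with its overlapping gene TMEM198B in the 32. Genes that vary more than the typical scatter used in the simulation may also account for the 32. Under the headings a protective effect would raise the 30 and not the 32. The test therefore leaves both a protective effect and such variation open, and replicate libraries would be needed to separate them.

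HMOX1 and the medians of the NRF2, AhR and heat shock lists were higher in the library labelled DEHP than in both others, though HMOX1 alone of these lists passed 2-fold and ABCC1 of the NRF2 list was at 0.792-fold of Control (0.693 to 0.905). Counting noise is argued against by the interval limit of the HMOX1 ratio nearest to 1, which was 2.58 at the lower of both comparisons. GC content and length are argued against as the whole cause, since the corrected NRF2 median was 0.150 on the log2 scale and still outside random lists against both other libraries. An exchange of the 2 treated libraries stays open, because 2 of 2 headings name the other treatment and no value in the tables decides. Under the labels the pattern would be a response to DEHP that KRG limits, and under the headings a response to KRG with DEHP that DEHP alone lacks; either is a hypothesis that these 3 libraries cannot test without a check of sample identity, replicates and a KRG-only library, and neither a difference of culture or library preparation nor RNA from other cells (the low-count liver genes had 20, 101 and 24 reads in Control, DEHP and DEHP+KRG) was tested as its source.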
